A study of Mus musculus with 6 samples.

How the data were processed

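RNA was measured by poly-A selected sequencing in 6 libraries of mouse bone marrow-derived macrophages, 3 exposed to resolvin D1 (RvD1) for 6 h and 3 untreated. Groups and replicate numbers were taken from the sample titles, and each column of the table was matched to its sample by the group and number in the column name. Per the labels' protocols, libraries were made from 100 to 400 ng of total RNA with a TruSeq kit and sequenced on an Illumina HiSeq instrument. TopHat2 2.0.7 and the mm10 genome build are named in the submitters' processing notes. The read counter, the annotation release and the software used for normalization are not given in the sources used here.

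The authors deposited 1 table of 38087 Ensembl genes, with 1 column per library described only as normalized, per the file headers. Its values were read as log2 normalized read numbers, which was tested on the deposited values: none lay below 0, the highest was 17.4, and the antilogs summed to between 12.4 and 12.8 M in every library. Between 49.6% and 51.6% of the genes of a library were listed at exactly 0, the log2 of a floor of 1 normalized read, and 17042 genes were listed at 0 in all 6 libraries. A value of 0 therefore stands for a normalized read number of 1 or less, and folds of genes near that floor understate the change. Low values clustered at multiples of a step that stands for 1 read. From that step the depth was estimated at 10.1, 14.3 and 9.05 M reads for untreated replicates 1, 2 and 3, and at 16.3, 11.2 and 12.8 M for RvD1 replicates 1, 2 and 3. Only 40.6% to 51.5% of the values worth up to 20 reads lay within 0.02 reads of a whole number, so whole reads were not recovered and no count test was run.

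Differential expression was tested with limma 3.58.1 in R 4.3.3 on the log2 values as deposited, without further scaling, for the 18899 genes above 0 in at least 3 libraries. The model held the treatment alone, the variance prior followed the mean level (limma-trend), tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The test for log2 values, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined; alternatives chosen after seeing the data are named as such where their values are given. Alternatives reserved for counts were not used, because the table holds log2 values. Standard errors and 95% intervals came from the moderated fit, with 4 residual degrees of freedom and 4.62 prior degrees of freedom borrowed across genes. The labels do not say whether the 3 libraries of a group came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical. Each pair of libraries differed by 4.36 to 16.4 times the variance expected from counting reads, over genes with at least 100 estimated reads in both, so none was treated as a repeat of another.

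Sets of genes were tested with camera, part of limma, at its preset inter-gene correlation of 0.01, over 33 lists (24 of functions and 9 of cell type markers), with Benjamini-Hochberg adjustment across lists. Results with a correlation estimated from the residuals and from the directional fry test stand beside each list that passed in this test. The named genes were the 10 highest and 10 lowest log2 fold changes among genes past the test whose groups did not overlap, the 5 smallest p-values in each direction, up to 4 members past the test per list (or the member with the smallest p, as values only), and Fpr2, Vegfa, Ccl2, Il10, Tnf, Arg1, Mrc1 and Il1b. Numbered clones and gene models taken by that rule were left out of the text.

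Coordinates, biotypes, transcript lengths and GC content came from GENCODE M21 on the mm10 assembly, in which 36308 of the 38087 identifiers (95.3%) were found. For the correction for length and GC content, splines with 4 knots in log2 length of the longest transcript and in GC content were fitted to each library's deviation from the gene means and subtracted. The tests were checked on simulated data of 18474 genes built from the libraries' own levels. At a mean log2 value of at least 5, 67 of 78 genes changed by 1.5-fold (85.9%) and 63 of 65 changed by 2-fold (96.9%) were recovered. Under that level 0 of 21 and 10 of 32 (31.2%) were recovered. Of 148 calls, 8 were of unchanged genes. In the same data the list given a shift of 0.3 was called, and 1 of the 33 lists was called without a shift. The simulated genes were drawn independently, with 1 dispersion and no trend with length or GC content. In the real data the estimated correlation was 0.803 for interferon-stimulated genes. The simulation therefore does not check the list test for lists whose genes move together. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.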

Results

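Gene expression was profiled in macrophages grown from the bone marrow of male C57BL/6J mice aged 8 to 10 weeks. The cells were differentiated for 7 days with 10 ng/ml of macrophage colony-stimulating factor, re-plated without it for 24 h, and either exposed to 10 nM RvD1 for 6 h or left untreated, with 3 libraries per group. RvD1 is a lipid mediator formed from docosahexaenoic acid that acts through the receptor ALX/FPR2, and the series concerns that receptor in myeloid cells during recovery of blood supply to an ischemic limb. The comparison addresses which transcripts differ in macrophages 6 h after RvD1. No vehicle for the untreated cultures is described in the labels. Estimated depth ranged from 9.05 to 14.3 M reads in the untreated libraries and from 11.2 to 16.3 M in the RvD1 libraries.

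With RvD1, 8 of 30 genes of a glycolysis and hypoxia list rose and 4 of 24 genes of an antioxidant (NRF2) list fell, while the other 22 and 20 did not pass the limma test. Ankrd37, a target of hypoxia-inducible factor, rose 3.19-fold (95% interval 2.43 to 4.19, n = 3 per group; limma adjusted p = 0.0217). Arg2, the mitochondrial arginase, rose 3.91-fold (2.29 to 6.68; limma adjusted p = 0.0413) from a low level of 2.70 ± 0.55 (log2, SD, n = 3). Among the genes that fell, the carbonyl reductase Cbr3 reached 0.492 of its untreated level (0.421 to 0.577; limma adjusted p = 0.0217). The stress cytokine Gdf15 reached 0.511 (0.422 to 0.618; limma adjusted p = 0.0244).

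In all, 106 of 18899 tested genes were higher and 105 lower with RvD1 (limma, Benjamini-Hochberg adjusted). The groups did not overlap in any of these 211 genes. The median change was 0.44 on the log2 scale for genes that rose and -0.43 for genes that fell. A change of at least 1.5-fold was seen in 28 of the higher and 24 of the lower genes, and 10 genes changed at least 2-fold. Across all tested genes the groups were apart in 4802 (25.4%), where chance gives 10%. Leaving out RvD1 replicate 1 gave 451 calls, 191 of them shared with the 211. Leaving out untreated replicate 1, 2 or 3 gave 5, 3 and 0 calls, of which 5, 0 and 0 were among the 211. Leaving out RvD1 replicate 2 or 3 gave 0 and 0 calls. In limma these 5 fits held 3440, 2748, 3045, 2623 and 3203 genes at an unadjusted p under 0.05. All 211 genes kept their direction with an unadjusted p under 0.05 in every fit without 1 library. This was largely fixed beforehand, since the 211 were picked for small p-values in these same libraries. Groups that do not overlap also cannot change sign when 1 library is left out.

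Among the other genes with the largest increases, Aqp9, a channel for water and glycerol, rose 2.11-fold (1.57 to 2.83; limma adjusted p = 0.0413). The arrestin family member Arrdc3 rose 2.10-fold (1.65 to 2.67; limma adjusted p = 0.0331). Lyst, a regulator of lysosome size, rose 1.81-fold, and Hilpda, a lipid droplet protein induced by hypoxia, 1.79-fold (1.59 to 2.01; limma adjusted p = 0.0185). Tnfsf15, a cytokine of the tumor necrosis factor family, was listed at 0 in every untreated library and at 1.93, 2.77 and 1.99 (log2) in RvD1 replicates 1, 2 and 3, so no fold was formed (limma adjusted p = 0.0478). The smallest p-values among the genes that rose included the adenylate kinase Ak4 (1.70-fold), the zinc finger protein Zfp292 (1.67-fold) and the kinase Stk17b (1.44-fold). On the lower side, Romo1, a mitochondrial inner membrane protein, reached 0.606 of its untreated level (0.496 to 0.740). The ribosomal protein gene Rps21 reached 0.655 (0.590 to 0.728) and the tubulin Tubb2a 0.676 (0.625 to 0.730). The genes given here without a p of their own passed the limma test, with adjusted p between 0.0185 for Tubb2a and 0.0436 for Romo1.

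Of the 30 tested genes of the glycolysis and hypoxia list, 8 rose, 0 fell and 22 did not pass (12 higher and 1 lower adjusted over the list alone). The members that rose were Ankrd37, Egln3, Ero1l, Bnip3, Pfkfb3, Vegfa, Slc2a1 and Hif1a. Egln3, a prolyl hydroxylase that marks hypoxia-inducible factor for degradation, rose 1.88-fold (1.58 to 2.23; limma adjusted p = 0.0237). Ero1l, an oxidase of the endoplasmic reticulum, rose 1.43-fold, and Bnip3, a mitophagy receptor, 1.40-fold. The 5 members with negative values, looked up after the result was seen, were all glycolytic enzymes, and 25 members were positive. Gapdh, Pkm, Aldoa, Gpi1 and Eno1 had log2 fold changes of -0.18, -0.17, -0.11, -0.10 and -0.04 and did not pass over all genes. Hk1, Hk2, Pfkl, Pfkp, Tpi1, Pgk1, Pgam1 and Ldha lay between 0.01 and 0.19 and did not pass either. The rise of the list therefore does not show that the glycolytic enzymes rose as a group. The list as a whole was higher (median log2 fold change 0.16; camera in limma, adjusted p = 2.13e-07; adjusted p = 0.648 with an estimated correlation). It also moved in one direction by fry in limma (adjusted p = 0.0339). After a correction for transcript length and GC content, chosen after seeing the data, Ankrd37, Egln3, Vegfa and Slc2a1 still passed the limma test. The other 4 did not: Hif1a went from 0.33 (SE 0.05) to 0.17 (SE 0.04), Ero1l from 0.52 (SE 0.07) to 0.37 (SE 0.05), Bnip3 from 0.48 (SE 0.07) to 0.37 (SE 0.07) and Pfkfb3 from 0.48 (SE 0.07) to 0.44 (SE 0.07), with limma adjusted p = 0.194, 0.0614, 0.102 and 0.0585.

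**Figure D1:**
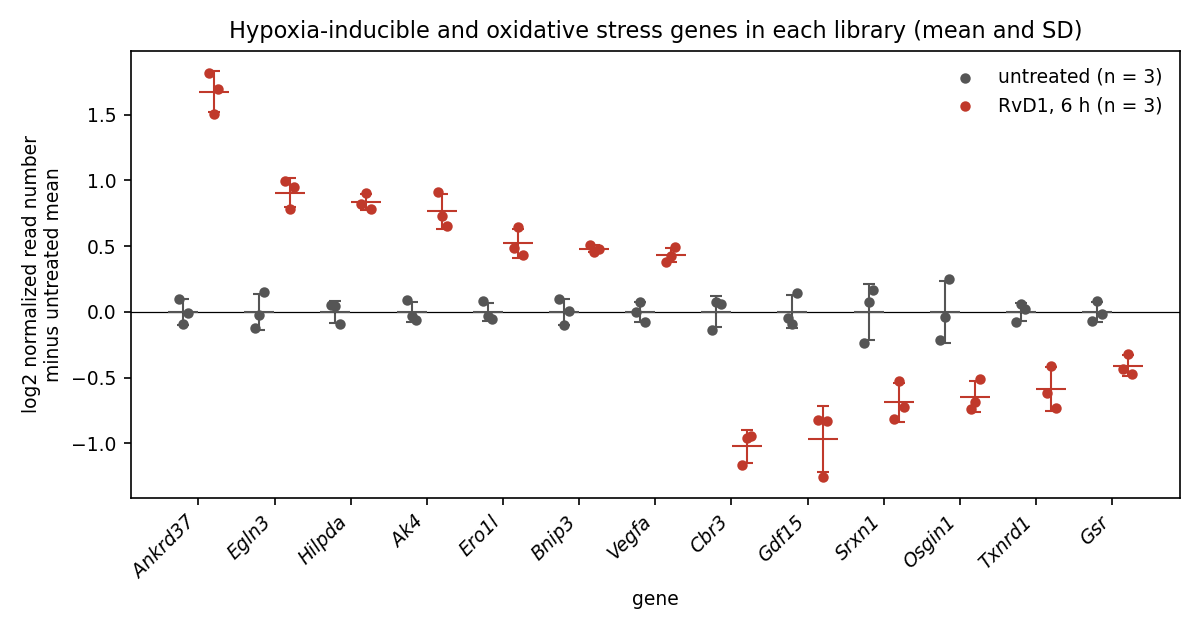
Log2 normalized read number of 7 genes that rose and 6 that fell, each library shown relative to the gene's untreated mean (points, libraries; dashes and bars, mean ± SD, n = 3 per group). The RvD1 libraries lie above every untreated library for Ankrd37 (log2 fold change 1.68) through Vegfa (0.43) and below every untreated library for Cbr3 (-1.02) through Gsr (-0.41).

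Vegfa, the main growth factor for blood vessels (chromosome 17, 46016993 to 46032369, minus strand, mm10, protein-coding), was 11.59 ± 0.07 in untreated and 12.02 ± 0.06 in RvD1 libraries (log2, SD, n = 3). It rose 1.35-fold (1.23 to 1.48; limma adjusted p = 0.0314) and was the 1 member of the 24 angiogenic factors past the test. The angiogenic list did not pass (median log2 fold change 0.09, camera in limma, adjusted p = 0.141). It passed by camera without RvD1 replicate 3 (adjusted p = 0.0149) and with a replicate block (0.0231). With an estimated correlation these were adjusted p = 0.678 and 0.595. It also passed by camera with the block and the length and GC correction together. By the mixed fry test, which takes changes in either direction, it was 1 of 13 lists that passed (adjusted p = 0.000186). The matrix remodelling list of 27 genes did not pass either (median 0.11, camera in limma, adjusted p = 0.0650), but did after the length and GC correction (0.0182), under quantile normalization (0.0283), with a replicate block (0.00534) and without RvD1 replicate 3 (0.0265). With an estimated correlation these were adjusted p = 0.502, 0.572, 0.525 and 0.678. Fpr2, which encodes the receptor (chromosome 17, 17887824 to 17893952, plus strand), stood at 4.71 ± 0.69 and 4.73 ± 0.32 (log2 fold change 0.02, 95% interval -0.77 to 0.80). Of the 9 tested RvD1 and chemoattractant receptors, 0 passed the limma test over all genes (1 higher and 1 lower at an unadjusted p under 0.05) and 1 was higher adjusted over the list alone. The chemokine Ccl2 had a log2 fold change of 0.38 (0.05 to 0.70; limma adjusted p = 0.191) and the cytokine Il1b one of 1.49 (0.37 to 2.61; limma adjusted p = 0.149). The intervals of Tnf (0.01, -0.28 to 0.29), Il10 (-0.21, -0.95 to 0.52), Arg1 (0.36, -0.02 to 0.75) and Mrc1 (0.11, -0.11 to 0.34) all included 0.

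NRF2 is a transcription factor that turns on antioxidant and detoxifying enzymes. Of the 24 genes of its list, 4 fell, 0 rose and 20 did not pass (13 lower and 1 higher adjusted over the list alone), and 23 had negative fold changes. Sulfiredoxin, Srxn1, reached 0.621 of its untreated level (0.520 to 0.741; limma adjusted p = 0.0386). Osgin1, an oxidative stress-induced growth inhibitor, reached 0.639, the thioredoxin reductase Txnrd1 0.666 (0.580 to 0.765; limma adjusted p = 0.0337), and the glutathione reductase Gsr 0.753. The 1 member with a positive value was Nfe2l2, which encodes NRF2 itself (log2 fold change 0.28, SE 0.06, limma adjusted p = 0.0609). The list was lower (median -0.22; camera in limma, adjusted p = 3.03e-08; adjusted p = 0.726 with an estimated correlation, and fry adjusted p = 0.232). After the length and GC correction 0 of the 24 passed over all genes (limma; 12 lower and 1 higher at an unadjusted p under 0.05), and Osgin1 went from -0.65 (SE 0.12) to -0.47 (SE 0.12), Srxn1 from -0.69 (SE 0.11) to -0.62 (SE 0.11), Gsr from -0.41 (SE 0.06) to -0.40 (SE 0.06) and Txnrd1 from -0.59 (SE 0.09) to -0.60 (SE 0.09), with limma adjusted p = 0.177, 0.0937, 0.0641 and 0.0590.

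Of 40 cytosolic ribosomal protein genes, 3 fell, 0 rose and 37 did not pass (17 lower adjusted over the list alone). These were Rpl38 (log2 fold change -0.48, SE 0.08), Rps15 (-0.35, SE 0.06) and Rpl37 (-0.34, SE 0.06). The list had a median of -0.14 (camera in limma, adjusted p = 6.37e-10; adjusted p = 0.849 with an estimated correlation, and fry adjusted p = 0.180). Subunits of the respiratory chain and ATP synthase were lower as a list as well (median -0.09; camera in limma, adjusted p = 0.000285; adjusted p = 0.648 with an estimated correlation, and fry adjusted p = 0.0339). Of its 34 members, Cox4i1 fell (-0.31, SE 0.05; limma adjusted p = 0.0338), and 6 were lower and 2 higher adjusted over the list alone. After the length and GC correction the median of the respiratory list was -0.04 (camera in limma, adjusted p = 0.00286, and adjusted p = 0.613 with an estimated correlation) and that of the ribosomal list -0.08 (adjusted p = 0.000122, and adjusted p = 0.739 with an estimated correlation). After it 0 members of either list passed in limma (12 lower and 2 higher ribosomal, 8 lower and 2 higher respiratory genes at an unadjusted p under 0.05), with values of -0.23 (SE 0.08) for Rpl38, -0.09 (SE 0.05) for Rps15, -0.23 (SE 0.05) for Rpl37 and -0.10 (SE 0.05) for Cox4i1.

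Fold changes followed transcript length and GC content across genes. Over 13024 genes with a mean log2 value of at least 5, Spearman's rho with the log2 fold change was 0.352 for length and -0.571 for GC content, where genes are not independent replicates. Transcripts over 8 kb had a median log2 fold change of 0.18 (31 higher and 0 lower genes), and those under 1 kb one of -0.09 (8 higher and 43 lower). The median longest transcript was 5456.5 bases for genes that rose and 1260 bases for genes that fell, against 2759 for all tested genes with an annotation. The slope per SD of log2 length was -0.02, -0.01 and -0.03 in untreated replicates 1, 2 and 3 and 0.02 in each RvD1 replicate. The slope per SD of GC content was 0.04, 0.06 and 0.05 in untreated replicates 1, 2 and 3, and -0.01, -0.11 and -0.03 in the RvD1 replicates, where replicate 2 stood apart. The correction left 18 genes higher and 18 lower, 32 of them among the 211. All 209 annotated genes of the 211 kept their direction, and their median size went from 0.43 to 0.30. Among the named genes, Hilpda, Ak4, Zfp292, Trib3, Cbr3, Gdf15, Tubb2a and Rps21 still passed, besides the hypoxia genes above. Romo1 went from -0.72 (SE 0.13) to -0.47 (SE 0.13) and Itga4 from 0.53 (SE 0.09) to 0.28 (SE 0.09), and with these smaller folds neither passed (limma adjusted p = 0.206 and 0.301). Lyst went from 0.85 (SE 0.11) to 0.64 (SE 0.11) and Arrdc3 from 1.07 (SE 0.15) to 0.91 (SE 0.15), and neither passed (limma adjusted p = 0.0721 and 0.0691). The same held for Stk17b, from 0.53 (SE 0.06) to 0.37 (SE 0.06), and Tnfsf15 (limma adjusted p = 0.0641 and 0.102). Arg2 went from 1.97 (SE 0.34) to 1.94 (SE 0.34) and Aqp9 from 1.08 (SE 0.19) to 1.03 (SE 0.18), and their calls ended with little change in either, as fewer genes had small p-values (limma adjusted p = 0.0859 and 0.0868).

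**Figure D2:**
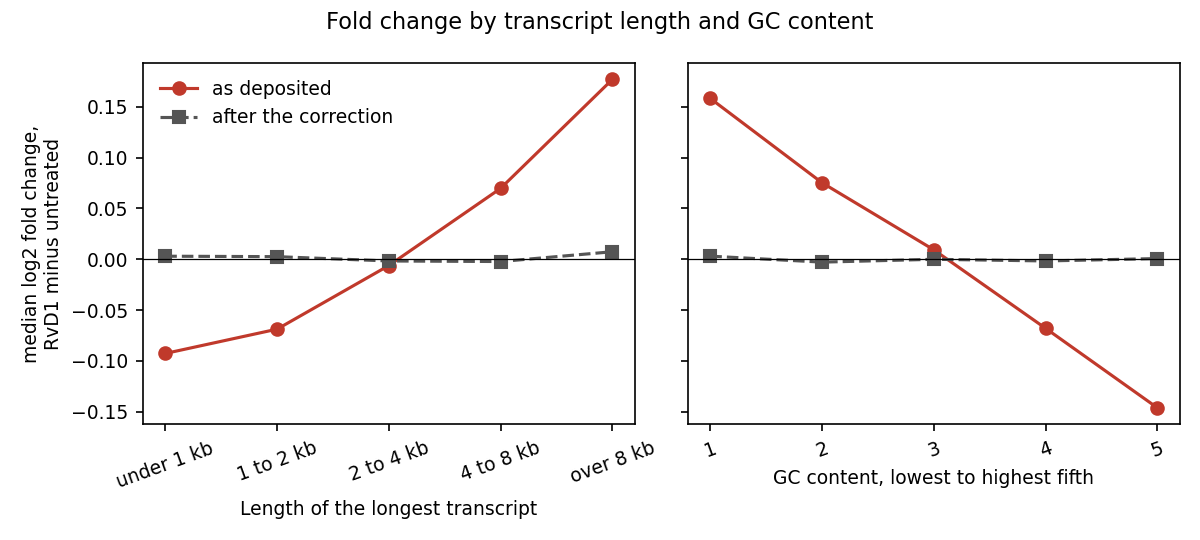
Median log2 fold change (RvD1 minus untreated) of genes binned by the length of their longest transcript (left) and by GC content in bins of equal size (right), as deposited and after the correction for both. The medians run from -0.09 under 1 kb to 0.18 over 8 kb and from 0.16 in the lowest to -0.15 in the highest GC bin, and lie within 0.01 of 0 after the correction.

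Genes of cholesterol synthesis and uptake were lower as a list (median -0.24, 23 of 25 negative; camera in limma, adjusted p = 2.30e-05; adjusted p = 0.849 with an estimated correlation, and fry adjusted p = 0.405), but 0 of 25 passed alone (limma; 8 lower at an unadjusted p under 0.05). The cell cycle list was lower too (median -0.09, 31 of 39 negative; camera in limma, adjusted p = 0.00154; adjusted p = 0.944 with an estimated correlation, and fry adjusted p = 0.636). Its 1 member past the test, the mitotic cyclin Ccnb2, reached 0.672 of its untreated level (0.571 to 0.790; limma adjusted p = 0.0446), and went from -0.57 (SE 0.10) to -0.56 (SE 0.10) after the length and GC correction (limma adjusted p = 0.0895). The cell cycle call ended without untreated replicate 1 (camera in limma, adjusted p = 0.223) and without RvD1 replicate 3 (adjusted p = 0.0503).

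Lists of immune signalling genes were higher as a whole, while no single member passed. For interferon-stimulated genes the median was 0.32, with 28 of 30 positive (camera in limma, adjusted p = 0.00154; adjusted p = 0.944 with an estimated correlation, and fry adjusted p = 0.767), and 6 were higher at an unadjusted p under 0.05 in limma. Rsad2, an antiviral enzyme, had a log2 fold change of 1.02 (SE 0.38, limma adjusted p = 0.184). The list's mean was 6.48, 6.47 and 7.49 in untreated and 6.76, 7.26 and 7.82 in RvD1 replicates 1, 2 and 3, so the groups overlapped. Inflammatory cytokines and NF-kB targets had a median of 0.16 with 25 of 28 positive (camera in limma, adjusted p = 0.00738; adjusted p = 0.849 with an estimated correlation, and fry adjusted p = 0.405). Their smallest p belonged to Tnfaip3, a brake on NF-kB (0.24, SE 0.05, limma adjusted p = 0.0710), and 7 were higher at an unadjusted p under 0.05. Chemokines had a median of 0.38 with 17 of 21 positive (camera in limma, adjusted p = 0.0227; adjusted p = 0.726 with an estimated correlation, and fry adjusted p = 0.423). Their smallest p belonged to Ccl7 (0.64, SE 0.18, limma adjusted p = 0.102), with 4 higher and 1 lower at an unadjusted p under 0.05. The interferon call ended without untreated replicate 1 (camera adjusted p = 0.0817), untreated replicate 2 (0.0920) or RvD1 replicate 3 (0.344). The cytokine call ended without untreated replicate 1 (0.257) or RvD1 replicate 3 (0.0624), and the chemokine call without untreated replicate 2 (0.0513), RvD1 replicate 1 (0.0880) or RvD1 replicate 3 (0.104). The chemokine call also ended when the 7 tested members that stand in other lists were left out, namely Cxcl1, Cxcl2, Ccl2, Cxcl10, Cxcl12, Ccl17 and Ccl22 (median 0.22 over the other 14, camera in limma, adjusted p = 0.234).

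**Figure D3:**
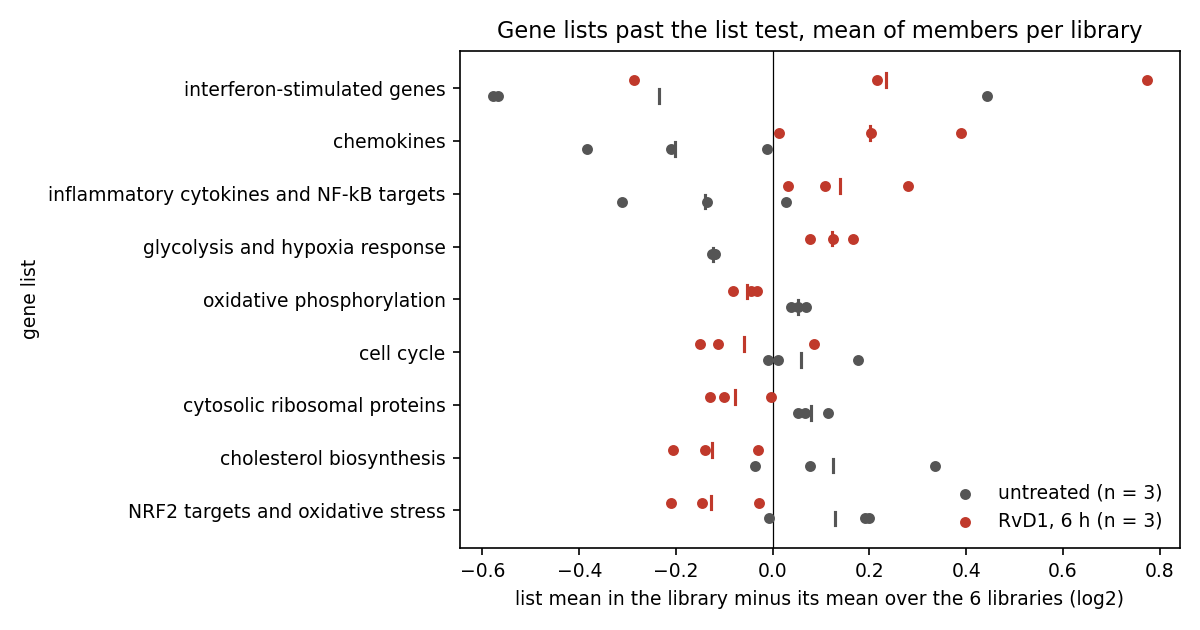
Mean log2 value of the members of each list past the list test, in each library, minus the list's mean over the 6 libraries (points, libraries; ticks, group means). The hypoxia list lies between -0.13 and -0.12 in the untreated and between 0.08 and 0.17 in the RvD1 libraries, while the interferon, cell cycle and cholesterol lists overlap between groups.

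Some genes outside these lists' calls also changed. In the unfolded protein and ATF4 list of 31 genes, the pseudokinase Trib3 rose 1.58-fold (1.33 to 1.87) and the chaperone component Sdf2l1 reached 0.745 of its untreated level (0.668 to 0.831; limma adjusted p = 0.0386 for both). Adjusted over the list alone, 5 were higher and 1 lower. The list did not pass as deposited (camera in limma, adjusted p = 0.214) but did after the length and GC correction (adjusted p = 0.0413; 0.646 with an estimated correlation), which moved Sdf2l1 from -0.42 (SE 0.07) to -0.25 (SE 0.06) and ended its call (limma adjusted p = 0.160). Itga4, the integrin alpha 4 chain that mediates leukocyte adhesion, rose 1.44-fold (1.24 to 1.67; limma adjusted p = 0.0442), and Fosl2, a subunit of the AP-1 transcription factor, 1.24-fold (1.15 to 1.34; limma adjusted p = 0.0386). Their lists of migration genes (camera in limma, adjusted p = 0.944) and immediate early genes (0.391) did not pass as deposited. After the length and GC correction the immediate early list passed as higher (camera in limma, adjusted p = 0.000285; 0.502 with an estimated correlation), while Fosl2 went to 0.30 (SE 0.05; limma adjusted p = 0.0641). Klf4 (log2 fold change 0.31), Abca1 (0.48), Mfge8 (-0.29), S1pr1 (0.32) and Nfatc1 (0.27), each the member of its list with the smallest p, did not pass over all genes (limma adjusted p between 0.0596 for Nfatc1 and 0.0801 for Abca1).

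Markers of other cell types did not move as lists (0 of 9 past the test by camera in limma, 0 at an unadjusted p under 0.05). Stromal and fibroblast markers averaged 10.8, 10.6 and 10.7 in untreated and 11.1, 10.6 and 10.7 in RvD1 replicates 1, 2 and 3 (camera adjusted p = 0.220), next to an untreated mean of 12.4 for macrophage identity genes. Endothelial markers stood at 6.06, 5.41 and 5.90 against 6.99, 5.43 and 6.03 (adjusted p = 0.151). Neutrophil markers stood at 6.11, 6.64 and 7.68 against 6.48, 6.88 and 7.79 (adjusted p = 0.467). Some marker lists passed as higher when 1 library was left out (camera in limma). These were stromal markers without untreated replicate 1 (adjusted p = 0.0499), RvD1 replicate 2 (0.0103) or RvD1 replicate 3 (0.0498), and neutrophil markers without untreated replicate 3 (0.000451) or RvD1 replicate 1 (0.0352). Without RvD1 replicate 2, endothelial (adjusted p = 7.35e-05) and mast cell markers (0.00721) passed as well. These last 2 lists also passed after the length and GC correction (camera in limma, adjusted p = 0.0215 and 0.0413, and adjusted p = 0.764 and 0.696 with an estimated correlation). With a replicate block, 4 of the 9 passed as higher (camera in limma), namely neutrophil (adjusted p = 0.0202), stromal (0.0231), endothelial (0.0209) and mast cell markers (0.0383). With an estimated correlation the lowest adjusted p of a marker list in these fits was 0.525, for mast cell markers with the block (camera in limma).

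Taken over all 33 lists, 4 moved higher and 5 lower with RvD1 by camera in limma at the preset correlation, and 0 passed with an estimated correlation (2 at an unadjusted p under 0.05). The other splits of the 6 libraries into 3 and 3 moved up to 18 lists, and 8 of the 10 splits moved at least 9. For genes the highest other split gave 14 calls against 211. Each other split mixes treated and untreated libraries on both sides. Any difference between the groups then adds to its spread and can lower its calls. At an unadjusted p under 0.05 in limma the other splits held up to 1700 genes, against 3768 for the split by treatment. With 10 splits a share under 0.05 cannot be reached.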

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

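The corrections for length and GC content, the filter at a mean log2 value of 5, the array weights and the rescalings of the list tests were chosen after seeing the data. The counts of higher and lower genes stayed within 1.5 times the reported 106 and 105 with a pseudocount of 0.1 (77 and 83) or 0.5 (98 and 95), a mean of at least 5 normalized reads (131 and 143), median-of-ratios rescaling (105 and 111), quantile normalization (105 and 129) and robust variance moderation (126 and 127). They were 5 and 7 without a filter, where 21045 genes were tested, and 218 and 246 with the mean log2 filter, where 13176 were tested. They were 1 and 0 without the variance trend (3113 genes at an unadjusted p under 0.05 in limma) and 263 and 303 with array weights, and the cause was not tested. By construction, stricter or looser limits gave 28 and 24 (at least 1.5-fold), 506 and 505 (adjusted p under 0.1) or 0 and 0 (adjusted p under 0.01 in limma, with 3768 genes at an unadjusted p under 0.05). Leaving out 1 library at a time, with fewer samples, gave 0 to 239 higher and 0 to 212 lower genes. The length and GC correction gave 18 and 18, and the same correction with the replicate block 357 and 401. The alternatives planned for counts (other size factors, other count tests and count filters) were not run, since the table holds log2 values. In these settings all tested genes of the 211 kept their direction.

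The list count of 9 became 0 with an estimated correlation (camera in limma, 2 lists at an unadjusted p under 0.05), 2 by the directional and 13 by the mixed fry test, 14 after the length and GC correction and 18 with that correction and the block. The lists added by the correction were immediate early genes, unfolded protein and ATF4 response, matrix remodelling and the endothelial and mast cell markers. Leaving out 1 library gave 7 to 12. Among the lists added there were lysosome genes without untreated 1 (camera in limma, adjusted p = 0.0225) and macrophage identity genes without untreated 3 (0.0313) or RvD1 1 (0.0466). With an estimated correlation these were adjusted p = 0.902, 0.765 and 0.911. It was 8 with genes shared between lists left out, 9 under median-of-ratios rescaling and 10 under quantile normalization. Each of the 9 lists kept the sign of its direction in every directional setting. The cause of these moves was not tested.

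The replicate numbers were not taken as pairs. Over 13176 genes, the deviations of same-numbered libraries from their group means correlated at 0.301, -0.0801 and 0.417 for numbers 1, 2 and 3. Untreated 3 correlated at -0.383 with RvD1 1, untreated 1 at -0.393 with RvD1 3, and untreated 2 at 0.0879 with RvD1 1. Numbers 1 and 3 correlated best with their own number. Number 2 did not. Deviations cancel out within a group, so the values of all 3 numbers are tied to each other. These correlations alone therefore cannot decide for or against pairs. Whether the numbers mark pairs stays open, as the labels do not say. With the replicate block there were 1049 higher and 847 lower genes, including all 211, and 15 lists, among them 4 of the 9 marker lists.

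Among the named genes that did not pass, some changed sign, none with an adjusted p below the 0.517 of Mrc1 in limma, and the cause was not tested. Fpr2 was at -0.19, -0.17, -0.11 and -0.03 without untreated 1, untreated 2, RvD1 2 and RvD1 3, at -0.0323 after the length and GC correction, with or without the block, and at most at 0.41 (without untreated 3). Tnf was at -0.0869 and -0.0850 without untreated 1 and RvD1 2, at -0.0376 with array weights, and at most at 0.0975 (without RvD1 3). Mrc1 was at -0.0380 after the correction, with or without the block. At these depths the simulated data showed that 1.5-fold changes under a mean log2 value of 5 were not detectable (0 of 21 recovered).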

Other observations

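The genes and families of the first paragraphs and the test of ribosomal protein pseudogenes were chosen only after the results were seen, as was the count of genes over other splits. Some genes known to respond to low oxygen were picked from among the genes that rose, so they say nothing on such genes as a group. Narf rose 1.76-fold (1.51 to 2.04; limma adjusted p = 0.0228), and the histone demethylase Kdm3a had a log2 fold change of 0.59 (SE 0.09; limma adjusted p = 0.0337). The collagen lysyl hydroxylase Plod2 was at 0.42 (SE 0.07; limma adjusted p = 0.0413). After the length and GC correction Narf still passed (0.78; limma adjusted p = 0.0284), but Kdm3a (0.48; 0.0691) and Plod2 (0.30; 0.193) did not. Several genes of secreted and surface proteins, chosen as genes of mesenchymal cells seen among the calls, changed too. The hyaluronan synthase Has2 rose 1.65-fold (1.41 to 1.93) and the cytokine Lif 1.64-fold (1.40 to 1.91), and the endothelin receptor Ednrb reached 0.652 of its untreated level (0.573 to 0.742; limma adjusted p = 0.0314 for each). After the correction Lif and Ednrb still passed, and Has2 did not (0.56; limma adjusted p = 0.0895). On the lower side, the stress-responsive ubiquitin ligase Trim16 reached 0.660, the channel Panx1 0.626 and the lipoprotein receptor Lrp8 0.631 (limma adjusted p between 0.0314 for Trim16 and 0.0337 for Panx1).

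Tubulin genes shared a sign. Of 11 alpha and beta tubulin genes, 2 fell, Tubb2a and Tubb2b (0.709 of the untreated level, 0.646 to 0.779; limma adjusted p = 0.0237), and 0 had a positive fold change, also under quantile normalization and the length and GC correction. The correction took the median of the tubulins from -0.29 to -0.17, and both genes still passed after it (limma adjusted p = 0.0284 for each). Of 25 histone lysine methyltransferase and demethylase genes, 5 rose (Kdm3a, Mll3, Mll5, Setd2 and Kdm5a), and 21 were positive, as were 20 under quantile normalization. After the length and GC correction 0 of the 25 passed in limma (8 higher and 1 lower at an unadjusted p under 0.05) and 19 were positive, with the median going from 0.16 to 0.05. Pseudogenes made up 22 of 103 annotated lower and 7 of 106 annotated higher genes, against 2640 of 18549 tested (Fisher's exact test, two-sided, odds ratios 1.64, p = 0.0466, and 0.425, p = 0.0245). That test takes genes as independent, although 7 ribosomal protein pseudogenes were among the lower genes. The trend with length and GC content was not removed for it. At a mean log2 value of at least 5, 8 genes under 1 kb were higher and 43 lower. Genes of fibroblasts stood at high levels in the untreated cultures, with Col1a1 at 14.21 ± 0.10, Col1a2 at 14.10 ± 0.12 and Col3a1 at 12.29 ± 0.17 (log2, SD, n = 3). Which cells of the cultures the changed RNAs came from, such as those of Has2, Lif and Ednrb, was not tested.

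The rise of the glycolysis and hypoxia list was weighed against the length and GC trend. With the trend removed, the median of the list was 0.18, against 0.16 before, and 26 of 30 members were positive. The list's means were then 10.35 to 10.38 in the untreated and 10.61 to 10.67 in the RvD1 libraries. These values argue against the trend as the whole cause of the rise. The list also passed camera in limma (adjusted p = 1.41e-15, and 0.312 with an estimated correlation). That call adds little, as camera at the preset correlation also moved lists in other splits of the libraries. Oxygen or cell density that differed between the cultures of the groups cannot be told apart from RvD1, since such a difference would follow the groups. The list's mean varied by 0.01 within the untreated libraries (range 0.00639) and differed by 0.25 between groups. A response to RvD1 itself may also explain the rise and stays a hypothesis.

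The fall of NRF2 targets was weighed against the same trend. With the trend removed, the list's median was -0.20, against -0.22 before, and 22 of 24 members were negative (camera in limma, adjusted p = 1.80e-09; 0.613 with an estimated correlation). The list's means did not overlap, but untreated replicate 1 (11.7379) stood beside RvD1 replicate 2 (11.7372). Since the median moved little, the trend is an unlikely whole cause of it, although 0 members passed alone after the correction. The camera call adds little, as camera at the preset correlation also moved lists in other splits of the libraries. A response to RvD1, or a difference in oxidative stress between the cultures, may be involved, and neither was tested.

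For the lower ribosomal protein mRNAs scaling is argued against, since the median of the list was -0.16 under quantile normalization, while the median of all tested genes lay at 0.00 (median-of-ratios rescaling left -0.14 as it was and tests little). For reads moved to processed pseudogenes, the prediction was a positive median of the pseudogenes. Of 177 tested ribosomal protein pseudogenes 146 were negative, with a median of -0.13 before the length and GC correction. Genes under 1 kb had a median of -0.09 as well, so this sign cannot decide the question. The length and GC trend cannot be told apart from a specific change: with it removed the median was -0.0794 and camera passed in limma (adjusted p = 0.000122; 0.739 with an estimated correlation), but 0 members passed alone. The list's means then overlapped, with untreated replicate 3 at 11.00 and RvD1 replicate 1 at 11.02, a condition added after the result was seen. Both parts of the criterion set beforehand against the trend, the camera call and a median below -0.05, were met, but neither looks at that overlap.

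The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The split by treatment called 211 genes and the highest other split 14, so 1 of the 10 gave as many. The other splits mix treated and untreated libraries on both sides, so a difference between the groups can lower their calls. Their gene counts therefore do not show what arises without such a difference. For the lists, 8 of the 10 splits moved at least as many as the real 9, and the highest other moved 18 (camera with the preset correlation).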
